A study of Mus musculus with 2 samples.

How the data were processed

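The series held 2 single-cell RNA libraries of CD45+ immune cells that had been isolated by fluorescence-activated sorting from subcutaneous tumours of C57BL/6 mice. CD45 is a surface protein of leukocytes, and the tumours grew from MC38-GFP, a mouse colon adenocarcinoma line that carries green fluorescent protein. Per the labels, each mouse received 50000 tumour cells and a sub-optimal dose of an antibody against the T cell inhibitory receptor PD-1, 100 ug on days 12, 15, 18 and 22. The response field of the labels put 1 library in the responder group and 1 in the non-responder group. No replicate numbers and no number of mice per library were given. Bulk RNA of the sorted tumour cells, which the labels mention, was not used here.

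Per the labels' protocols, cells were captured in droplets with the 10x Genomics Chromium 3' v3 kit, in which each molecule receives a cell barcode and a unique molecular identifier (UMI). Cell Ranger 1.1.0 and the mouse builds mm10 and GRCm38 stand in the submitters' processing notes. The annotation release and the rule that called cells were not given in the sources used here. The authors deposited a filtered matrix for each library whose values are UMI counts per gene and barcode, and the values were whole numbers in both files. The gene tables paired 27998 Ensembl identifiers with symbols. Coordinates came from GENCODE M21, an annotation of GRCm38, by Ensembl identifier, and 27722 of the identifiers were found there. Symbols, older ones such as Fam26f among them, are those of the files.

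The non-responder library held 2580 barcodes with 32032569 UMIs and a median of 11729 UMIs per barcode. The responder library held 4425 barcodes with 45866561 UMIs and a median of 10000. Barcodes with under 500 detected genes (4) or over 10% mitochondrial UMIs (61) were left out. Scrublet, as run in scanpy with an expected doublet share of 5%, marked 1 of the 7005 barcodes, so it did not work as a doublet filter and doublets were in effect not removed. After filtering, 2564 non-responder and 4376 responder cells remained.

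Counts were scaled to 10000 per cell, log-transformed and reduced to 30 principal components of 2000 variable genes, after genes seen in fewer than 3 cells had been dropped. The libraries were clustered together without batch correction, on 15 nearest neighbours with the Leiden method at resolution 1.0. Clusters that carried T cell or natural killer (NK) markers were pooled and clustered again, and these subclusters have an L before their number. Marker genes for 19 cell types were fixed before the data were examined, and 9 of them had no entry in the files. The scoring rule was set after the data had been seen. A marker counted at 50 CPM (counts scaled to a common total) or more with a UMI in at least 10% of the cluster's cells. A cluster with 50% or more of the T cell or NK markers was named for the larger share, and one with at least 75% of the macrophage or monocyte markers was named monocyte/macrophage-like. A cluster that met both the T cell and the macrophage limit was called mixed and kept out of both classes. Dendritic-like and fibroblast-like clusters needed at least 3 markers among their 10 leading genes. The dendritic rule came before the macrophage limit and also needed more dendritic than macrophage or monocyte markers there. Cluster 6, the whole dendritic-like class, carried 12 macrophage markers and so met the macrophage limit as well. A cluster that met the macrophage limit stayed unnamed if its UMI number was low and its 10 leading genes held no macrophage or monocyte marker, as did any cluster that met no rule. Against clusters outside its class, each cluster of the compared classes passed a check that its 10 leading genes held no more markers of another class than of its own. Against all other clusters, cluster 3 (macrophage-like) and cluster L3 (T cell-like) failed it, and the values without them were computed as well.

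Each share of cells has an exact Clopper-Pearson 95% interval, and a share of 0 also has the limit that 3 counts would give. For expression, counts were summed per library over the cells of a class and scaled to CPM of that sum, with exact Poisson 95% intervals. The log2 ratio, responder over non-responder, has a conditional exact binomial 95% interval. Where a library had no count, the ratio was taken against 3 counts, and among the alternatives no ratio was given where both libraries had 3 counts or fewer. All of these intervals cover counting error only. With 1 library per group, cells were not treated as replicates and no test between groups was made. Expression was compared in the macrophage-like and T cell-like classes, which alone among the named immune classes had at least 50 cells in each library.

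The 29 gene lists were fixed before the data were examined. A member was measured at 50 or more counts in the 2 libraries together, and 4 of the 379 listed genes had no entry in the files. A list's value was the median log2 ratio of its measured members with 5 CPM added to each value. Its interval came from the order of the members, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. The percentile is a description of these 2 libraries and not a test, and it takes no account of genes that change together. Lists with fewer than 3 measured members were given no median. The rule for named genes was also fixed beforehand. It ranked genes with at least 100 CPM in a library and a UMI in at least 5% of that library's class cells by the interval bound nearest 0, and took the first 12 in each direction. Mitochondrial, ribosomal, immunoglobulin, haemoglobin, T cell receptor V and predicted genes were left out of the ranking. Up to 4 members of each list were added, the largest and, where signs differed, the smallest ratios, together with the targets of imaging and therapy. Shares of cells with a UMI were computed after each cell had been thinned to 3000 UMIs, which left out 107 responder and 2 non-responder cells.

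On simulated counts of these libraries with 200 genes changed 2-fold, the intervals covered 95.6% of the ratios of 10853 genes in the macrophage-like class. All 200 changed genes had the right direction there. Lists of genes changed 2-fold, a log2 ratio of 1, came out at medians of 0.73 and -0.57 in that class, and at 1.03 and -0.91 in the T cell-like class, so list medians can understate a change. Of 20 unchanged lists 2 lay beyond the 95% limits of the random lists in the macrophage-like class and 1 in the T cell-like class. In the T cell-like class the coverage was 94.7% over 1690 genes, and 99.5% of the changed genes had the right direction. The alternatives fixed beforehand changed the clustering resolution, the number of variable genes, separate clustering of the libraries, the doublet, mitochondrial and gene filters, trimmed-mean (TMM) scaling with edgeR, thinning, equal weight per cell, the pseudocount, the count minimum and equal weight per cluster. Others were added after the data had been seen and concern high doublet scores and single clusters. The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.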

Results

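Single-cell RNA was counted in CD45+ cells sorted from MC38 tumours of mice under PD-1 blockade, with 1 library from the responder group and 1 from the non-responder group. The series title puts the myeloid cells of the tumour at the centre, so the comparisons ask how the immune cells, and macrophages first, differed between the groups. The 2564 filtered cells of the non-responder library had a median of 11749.5 UMIs, and the 4376 cells of the responder library had a median of 10043. Values are given as responder against non-responder. There was no replicate check for any difference, which separates these 2 libraries and not the response groups in general. Intervals in brackets cover counting error at the 95% level, except those of medians over genes, which come from the order of the genes. For a list with few measured members that interval is the full range of the members and covers less than 95%.

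The first comparison was of cell types. Both libraries consisted largely of monocyte/macrophage-like cells, which made up 93.9% [93.1-94.5] of the responder cells (4107) and 91.9% [90.8-92.9] of the non-responder cells (2356). T cell-like cells were 1.99% [1.60-2.45] and 2.34% [1.79-3.00], with overlapping intervals. Droplets with the markers of both T cells and macrophages were more frequent in the responder library, 2.35% [1.93-2.85] against 1.21% [0.823-1.71]. They are kept out of the T cell-like share. Counting them as T cells would make that share higher in the responder library, so its direction depends on this choice. Dendritic-like cells, which led with Ccl22, Cd209a and Ccr7, were 0.251% [0.126-0.449] and 2.93% [2.31-3.65]. NK cell-like cells, which led with Ncr1 and granzymes, were 0.0914% [0.0249-0.234] and 0.780% [0.477-1.202]. Fibroblast-like cells, which the CD45 gate should have removed, were 0.503% [0.315-0.760] and 0.780% [0.477-1.202]. Cluster 17, which stayed unnamed, held 0.960% [0.693-1.295] and 0.0780% [0.00945-0.281]. No B cell-like or neutrophil-like cluster was found. All shares are of CD45-sorted cells, so the gate sets the denominator.

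The dendritic-like share of the responder library depended on the clustering. It was 0.960% at resolution 0.5 and with 1000 variable genes, and 0.983% when each library was clustered on its own. The share left unnamed in the responder library was 0% at resolution 0.5, with 1000 variable genes and with cells of at least 1000 genes. It was 0.206% at resolution 2.0 and 1.5996% when each library was clustered on its own. In that last setting the responder library had no NK cell-like and no fibroblast-like cluster. Without the highest doublet scores, mixed droplets were 1.93% of the responder and 0.573% of the non-responder library.

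**Figure D1:**
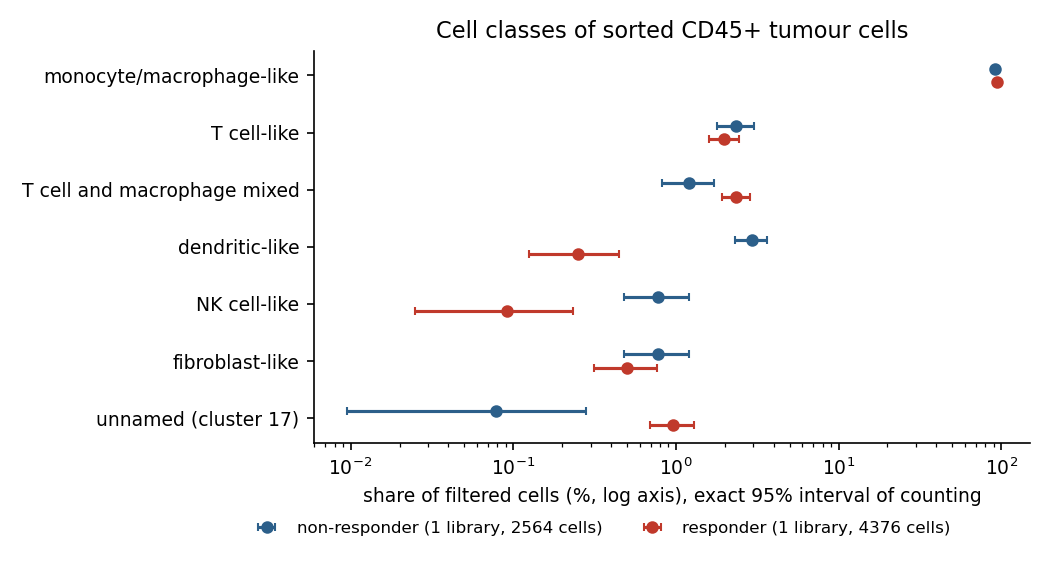
Share of filtered cells in each class as a percent on a log axis, with exact 95% intervals of counting, for the non-responder library (2564 cells) and the responder library (4376 cells). Macrophage-like cells were 91.9% and 93.9%, and the dendritic-like share was 2.93% in the non-responder and 0.251% in the responder library.

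The title names immuno-PET, an imaging method in which a labelled antibody fragment reports where its target is. The list of targets of imaging and therapy held CD8, CD11b, CD45 and the PD-1 axis. With each cell thinned to 3000 UMIs, Cd8a (GRCm38 chromosome 6, 71373427 to 71379173), a chain of CD8, had a UMI in 3.87% [3.31-4.49] of responder and 2.11% [1.59-2.74] of non-responder cells of any class. The unthinned shares were 6.22% and 2.85%. In macrophage-like cells, which should lack Cd8a, the thinned shares were 0.520% and 0.170% at median depths of 10105 and 11935.5 UMIs. Itgam (chromosome 7, 128062640 to 128118491), which encodes CD11b, had a UMI in 30.5% [29.1-31.9] and 37.4% [35.6-39.3] of all thinned cells, and in 63.0% and 73.7% unthinned. In T cell-like cells its thinned shares were 1.39% and 5%, at median depths of 3685 and 4910 UMIs. Cd274, the gene of the PD-1 ligand PD-L1, had a UMI in 14.1% [13.1-15.2] and 9.13% [8.05-10.3] of thinned cells, and in 35.3% and 22.0% unthinned. In thinned T cell-like cells a Cd274 UMI was seen in 0 of 72 responder cells, where 3 cells would be 4.17% and the exact upper bound is 4.99%, and in 6.67% of non-responder cells. Unthinned, the shares were 4.60% and 10%. Such bounds limit cells with a UMI, not cells that express the gene.

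The main comparison was within the monocyte/macrophage-like class, over 42871815 and 29364423 UMIs. Macrophage-like cells of the responder library had more RNA of antigen presentation and of genes that interferon-gamma induces, led by the T cell-attracting chemokine Cxcl9. Cxcl9 (chromosome 5, 92321347 to 92328079) was at 683.1 CPM [675.3-691.0] against 60.1 [57.3-62.9], a ratio of 11.4. Macrophage-like cells of the non-responder library had more RNA of lipid and lysosome genes and of matrix genes, Spp1 among both. Pmp22, which ranked first, is in neither list. Spp1 (chromosome 5, 104435118 to 104441050), which encodes osteopontin, was at 80.4 CPM [77.7-83.1] in the responder and 1552 [1538-1566] in the non-responder library, 19.3-fold higher in the latter. Clusters 0, 1 and 5 held most of the class in the non-responder library, and clusters 2, 3, 4, 7, 8, 10 and 15 most of it in the responder library.

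The 12 genes ranked first as higher in the responder library were Cxcl9, Ifitm1, Fam26f, Serpina3g, H2-Ab1, H2-Eb1, Ccl8, Il18bp, Slamf8, Ly6a, H2-Aa and Gbp2. Ifitm1, an interferon-induced membrane protein, had a log2 ratio of 3.47 [3.39-3.54] with 588.7 against 53.2 CPM. Fam26f was at 145.8 against 15.2 CPM and the protease inhibitor Serpina3g at 188.0 against 21.9. H2-Ab1 (chromosome 17, 34257689 to 34269419), a chain of MHC class II, was at 13269 CPM against 2290, with a log2 ratio of 2.53 [2.52-2.55]. Il18bp, a secreted inhibitor of interleukin 18, was at 299.9 against 53.7 CPM, and Ly6a, which encodes Sca-1, at 2861 against 579.1. The chemokine Ccl8 had a log2 ratio of 2.49, Slamf8 2.39 and the GTPase Gbp2 2.24. After thinning, a Cxcl9 UMI was found in 57.1% [55.6-58.7] of responder and 6.63% [5.66-7.71] of non-responder macrophage-like cells. In T cell-like cells the thinned Cxcl9 shares were 22.2% and 0 of 60, where 3 cells would be 5% and the exact upper bound is 5.96%. Unthinned, the macrophage shares of Cxcl9 were 74.0% and 13.1%.

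The 12 genes ranked first as higher in the non-responder library were Pmp22, Spp1, Fn1, Fcrls, Mmp12, Emp1, Pf4, Lsp1, Egr1, Hmox1, Cd9 and Ccl9. Pmp22 (chromosome 11, 63128982 to 63159547), known as a myelin protein gene, was at 2.85 CPM [2.36-3.40] against 100.97 [97.4-104.7], with a log2 ratio of -5.15. Fn1, which encodes fibronectin, was at 34.8 against 336.9 CPM, and the Fc receptor-like gene Fcrls at 91.3 against 733.3. The elastase gene Mmp12 had a log2 ratio of -2.79, Emp1 -2.45 and the chemokine Pf4 -2.27. Lsp1 was at -2.11, the immediate early gene Egr1 at -2.09, the haem oxygenase gene Hmox1 at -1.92, Cd9 at -1.70 and the chemokine Ccl9 at -1.69.

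**Figure D2:**
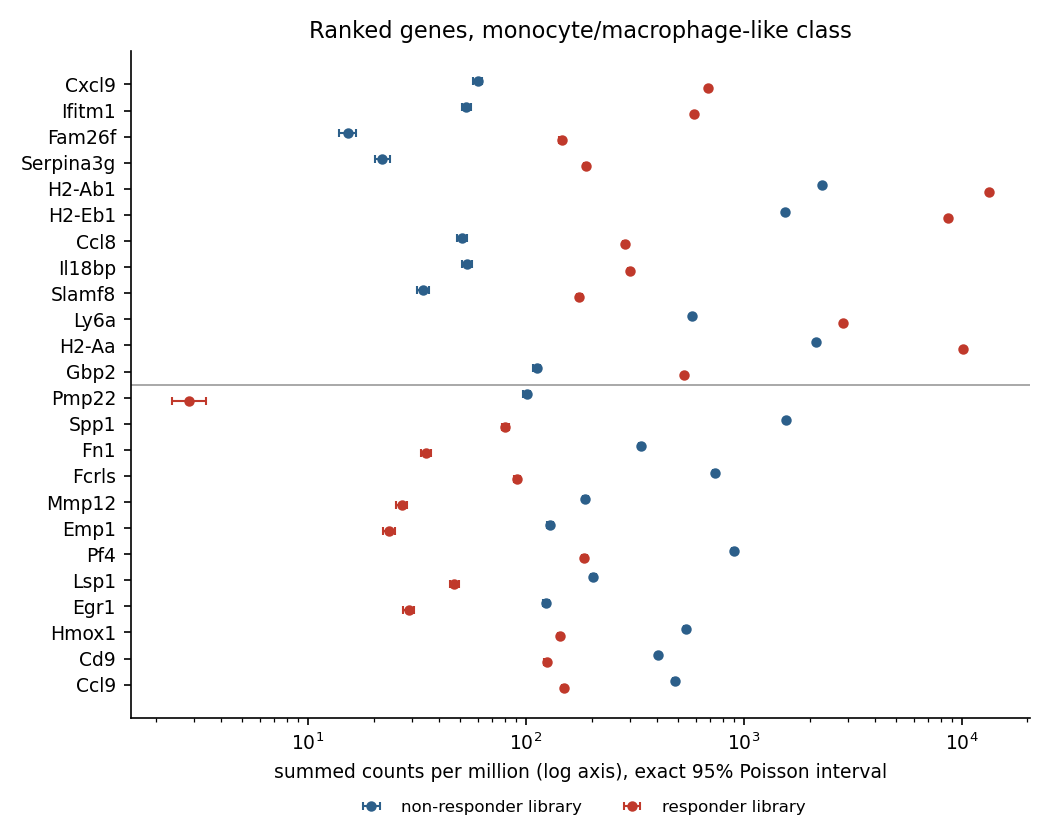
Summed counts in CPM (log axis) of the 24 ranked genes of the macrophage-like class, with exact 95% Poisson intervals, in each library. The 12 genes above the line were higher in the responder library, with Cxcl9 at 683.1 against 60.1, and the 12 below it higher in the non-responder library, with Spp1 at 1552 against 80.4.

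Clusters 1, 4, 7, 9 and 10 held at least 20 cells of each library, and the ranked genes were also compared within them. Cxcl9, Fam26f, H2-Ab1, H2-Eb1, Il18bp, Slamf8, Ly6a, H2-Aa and Gbp2 were higher in the responder library in 5 of the 5 clusters. Ifitm1, Serpina3g and Ccl8 were so in 4. Pmp22, Spp1, Fn1, Emp1 and Cd9 were lower in the responder library in 5 of 5, Mmp12, Lsp1, Egr1, Hmox1 and Ccl9 in 4, Fcrls in 3 and Pf4 in 2. Clusters 4, 7 and 10 held 22, 24 and 29 non-responder cells, which clustering had placed there by likeness to responder cells. The range of Cxcl9 over the clusters was 0.96 to 1.996, below the class value of 3.51, and that of Spp1 was -3.80 to -1.43.

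By gene list, each of the 10 measured genes of MHC class II presentation was higher in the responder library. Their median log2 ratio was 1.63 [0.49-2.48], at percentile 100 of the random lists. H2-Eb1 was at 8656 against 1546 CPM, and 7 members differed by more than 2-fold. The 14 genes of MHC class I presentation were likewise all higher, with a median of 0.76 [0.65-0.87] at percentile 100. Among them were the peptide transporter Tap1, at 296.1 against 139.5 CPM, and the immunoproteasome gene Psmb9, at 521.2 against 272.6. All 18 measured interferon-gamma induced genes were higher, with a median of 1.11 [0.76-1.84] at percentile 100. Type I interferon induced genes were split, with 14 of 22 higher and a median of 0.16 [-0.06 to 0.43] at percentile 99.9. The nucleic acid sensor Zbp1 had 380.2 against 188.9 CPM, Irf7 704.4 against 482.4, Ifit3 208.2 against 203.0 and the antiviral gene Rsad2 70.2 against 129.6.

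Classical (M1) activation genes were higher in 9 of 10 measured members, with a median of 0.48 [0.06-0.99] at percentile 100. Il1b was at 551.0 against 277.7 CPM and the costimulatory gene Cd86 at 167.1 against 127.5, and Tnf at 59.1 against 103.9. Alternative (M2) activation genes had a median of -0.88 [-1.29 to 0.11] at percentile 0, with 9 of 13 lower. Arg1, which encodes arginase 1, was at 331.4 against 790.0 CPM, the scavenger receptor gene Stab1 at 74.6 against 141.1, and Il4ra at 106.4 against 98.5. Checkpoint ligands and suppressive genes had a median of 0.34 [-0.49 to 0.90] at percentile 100, with 8 of 13 higher. Beside Il18bp they included Vsir, at 303.3 against 237.7 CPM, and Lgals9, at 155.4 against 214.5. The targets of imaging and therapy had a median of 0.37 [-0.33 to 0.90] at percentile 100, with 5 of 7 higher. Cd274 was at 54.7 CPM against 35.8, Ptprc, which encodes CD45, at 179.7 against 129.9 and Itgam at 135.1 against 171.6. Pdcd1lg2 was at 6.27 against 1.02 CPM. Pdcd1, the PD-1 gene, stood at 1.38 and 1.43 CPM, Cd8a at 2.15 and 0.715 and Cd8b1 at 2.19 and 0.579.

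Lipid and lysosome genes were lower in the responder library in 15 of 16 members, with a median of -0.92 [-1.65 to -0.51] at percentile 0. The fatty acid-binding protein gene Fabp5 was at 60.8 against 198.8 CPM and Ctsl at 318.3 against 414.1, and Apoe, the exception, was at 12278 against 10940. Of 16 hypoxia genes 14 were lower, with a median of -0.76 [-1.05 to -0.20] at percentile 0. The lipid droplet gene Hilpda was at 69.0 against 203.8 CPM, and the glucose transporter gene Slc2a1 at 65.2 against 140.5. Glycolysis genes were lower in 13 of 15, with a median of -0.33 [-0.44 to -0.10] at percentile 0.5 and Eno1 at 517.6 against 870.3 CPM. Matrix and angiogenesis genes were lower in 12 of 14, with a median of -0.34 [-2.59 to -0.06] at percentile 0.0400. Inflammatory chemokines had a median of -0.98 [-1.66 to 0.26] at percentile 0, with 10 of 14 lower. Ccl6 was at 138.3 against 331.1 CPM, while Ccl5 was at 1749 against 424.4. Proliferation genes were lower in 18 of 18 members, with a median of -0.27 [-0.40 to -0.16] at percentile 1.04. Tubb5 was at 664.7 against 876.5 CPM and Pcna at 74.2 against 109.3.

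C1q and resident-type genes had a median of -0.33 [-1.98 to 0.28] at percentile 0.530. The complement gene C1qb, at 10011 against 7845 CPM, and Ms4a7, at 1947 against 1592, were higher, and Cx3cr1, at 253.3 against 357.3, was lower. Monocyte genes had a median of -0.22 [-1.42 to 0.10] at percentile 2.32, with Ms4a4c at 650.8 against 405.0 CPM, Ly6c2 at 102.1 against 69.5 and S100a4 at 56.7 against 182.4. Oxidative phosphorylation genes had a median of -0.10 [-0.28 to 0.12] at percentile 52.5, with Cox5a at 556.9 against 377.7 CPM, Sdhb at 348.3 against 300.6, Atp5a1 at 300.2 against 398.3 and Ndufa4 at 80.9 against 168.7. NF-kB response genes had a median of 0.22 [0.00 to 0.32] at percentile 99.8, with Cd83 at 196.2 against 160.1 CPM, Sod2 at 145.8 against 132.2, Nfkbia at 490.9 against 591.0 and Ccrl2 at 167.9 against 210.2. Dissociation stress genes had a median of 0.12 [-0.29 to 0.27] at percentile 98.7, with Junb at 987.0 against 663.1 CPM, Dusp1 at 406.8 against 275.8 and Ier3 at 170.8 against 296.9.

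Lists of other cell types were read in this class as well. Neutrophil genes had a median of -0.95 [-3.36 to 1.14] at percentile 0 over 8 members, with S100a8 at 1.35 against 60.2 CPM and Clec4d at 62.9 against 131.7. The cytotoxic effector list had a median of -0.01 [-0.77 to 2.03] at percentile 71.1, with Ccl4 at 968.1 against 973.6 CPM and Ccl3 at 275.8 against 451.0. Exhaustion genes were at 0.25 [-0.59 to 0.72] and percentile 100. Naive and memory T cell genes were at 0.12 [-0.37 to 0.28] and percentile 97.8. Regulatory T cell genes were at 0.09 [-0.59 to 1.06] and percentile 91.5, with Capg at 661.4 against 792.7 CPM. Fibroblast genes were at -0.06 [-0.12 to 0.15] and percentile 39.3. The NK cell, tumour epithelial, endothelial and erythroid lists had too few measured members, 0, 2, 2 and 1.

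Weighting the 5 shared clusters equally moved several medians by more than 1.5-fold. MHC class II became 0.91, MHC class I 0.29, interferon-gamma 0.37, lipid and lysosome -0.44, hypoxia -0.45, inflammatory chemokines -0.42, M2 -0.13, M1 0.30, proliferation -0.02, checkpoint genes 0.15 and the imaging and therapy targets 0.17. Within the hypoxia list, cluster 9 was at -1.81 with 0 of 11 members higher, and clusters 1, 4, 7 and 10 were at 0.01, -0.09, -0.28 and -0.07, so cluster 9 carried the value. Glycolysis was at -1.20 and the neutrophil list at -2.67 in cluster 9. Type I interferon turned to -0.69, C1q and resident-type genes to 0.26, NF-kB to -0.07, exhaustion to -0.01 and oxidative phosphorylation to 0.02. TMM scaling added 0.12 to each log2 ratio of the class, which turned oxidative phosphorylation to 0.02 and the cytotoxic list to 0.11. In thinned cells the cytotoxic list turned to 0.34 and the regulatory T cell list to -0.17. Monocyte genes were -0.50 in thinned cells, -0.46 with a pseudocount of 1 CPM, -0.41 with equal cluster weight and -0.39 as a mean over cells. The matrix list was -0.71 in thinned cells and the neutrophil list -1.73 with a pseudocount of 1 CPM. With members of at least 1 count the neutrophil list was -0.09, and with cells of at least 1000 genes -0.57. Proliferation was -0.51 without the dividing clusters, -0.16 with TMM scaling and -0.10 without cluster 3. Over all alternatives the cytotoxic list ranged from -0.06 to 0.34, the regulatory T cell list from -0.17 to 0.76, dissociation stress from -0.0052 to 0.22 and fibroblast genes from -0.15 to 0.02.

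**Figure D3:**
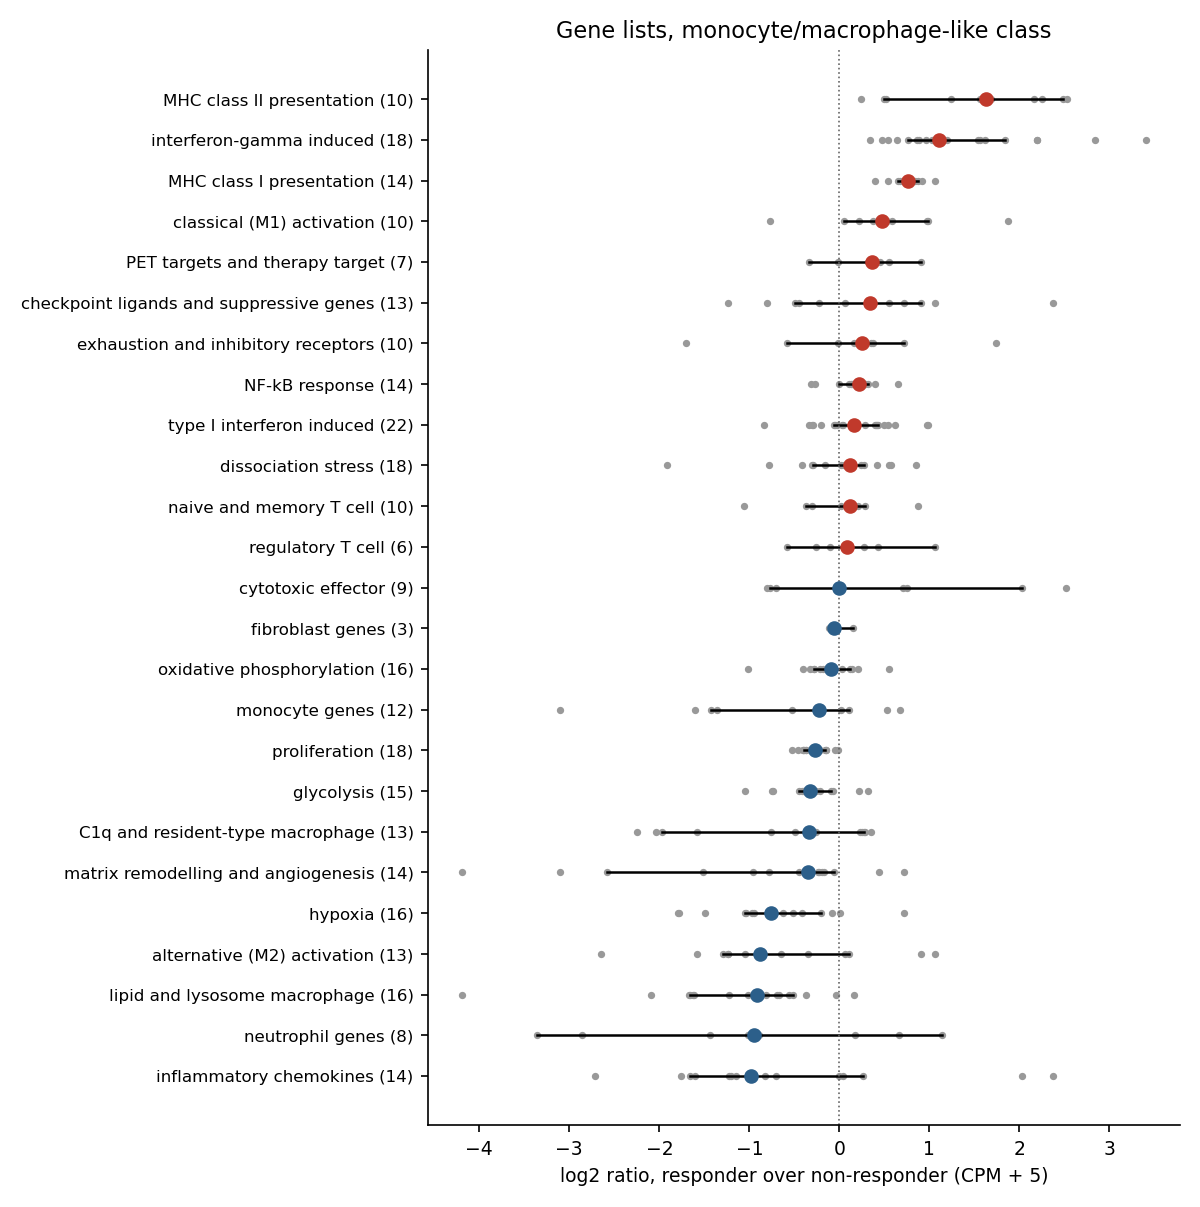
Median log2 ratio, responder over non-responder, of each measured gene list in the macrophage-like class, with intervals from the order of the members. MHC class II (1.63) and interferon-gamma induced genes (1.11) lie farthest to the responder side, and inflammatory chemokines (-0.98), neutrophil genes (-0.95) and lipid and lysosome genes (-0.92) farthest to the non-responder side.

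**Figure D4:**
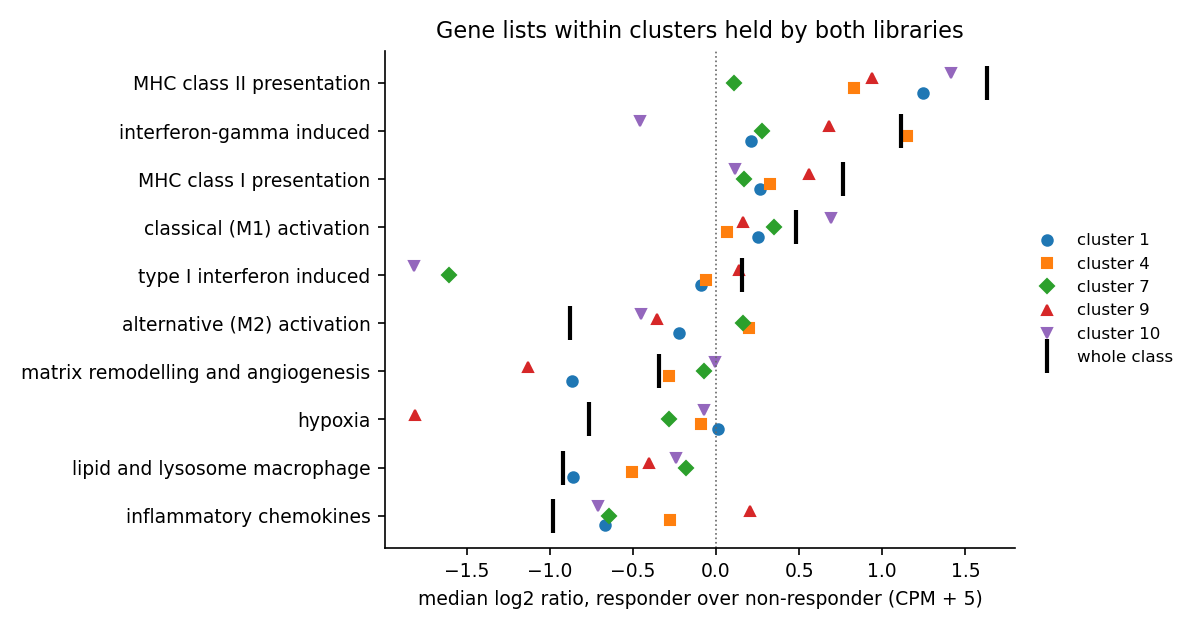
Median log2 ratio of gene lists within each macrophage-like cluster with at least 20 cells of both libraries. MHC class II was positive in all 5 clusters, from 0.11 in cluster 7 to 1.42 in cluster 10, and the interferon-gamma list was -0.46 in cluster 10.

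The last main comparison was within the T cell-like class, 87 responder and 60 non-responder cells with 370597 and 339772 UMIs. T cell-like cells of the responder library had more RNA of chemokines, granzymes A and B, Ifng and inhibitory receptors. Ccl4 (chromosome 11, 83662584 to 83664683) was at 4695 CPM [4477-4921] against 388.5 [325.1-460.7], a ratio of 12.1. Non-responder T cell-like cells had more RNA of Penk, of granzymes C and F and of the regulatory T cell genes Foxp3 and Ikzf2, with Foxp3 at 10.8 CPM [2.94-27.6] against 100.1 [69.3-139.8]. The class was made of different clusters in each library. Cluster L7 held 58 responder cells and 0 non-responder cells, L4 20 and 22, L3 7 and 19, and the Foxp3-bearing cluster L5 2 and 19.

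The 12 genes ranked first as higher in the responder library were Gzma, Ccl1, Ccl4, Serpine2, Ccl3, Havcr2, Lag3, Gzmb, Ifng, H2-Eb1, Ccl5 and H2-Ab1. Gzma (chromosome 13, 113093825 to 113100981) had 257 counts against 3, a log2 ratio of 6.30 [4.73-8.58], and a UMI in 9.20% of the responder cells. Ccl1 had 104 counts against 1, a log2 ratio of 6.58 [4.07-11.89], and Serpine2 had 89 against 3, a ratio of 4.77 [3.17-7.07]. The chemokine Ccl3 was at 1384 against 126.6 CPM and Ccl5 at 11247 against 2396. Gzmb (chromosome 14, 56258838 to 56262260), a serine protease of killer cells, was at 4083 CPM [3879-4294] against 676.9 [592.3-770.3]. The inhibitory receptor genes Havcr2 and Lag3 were at 334.6 against 23.5 and at 882.4 against 111.8 CPM. Ifng, the interferon-gamma gene, was at 720.5 CPM [636.6-812.3] against 108.9 [76.7-150.1]. After thinning, an Ifng UMI was found in 51.4% [39.3-63.4] and 20% [10.8-32.3] of T cell-like cells, against 0.0991% and 0.0425% of macrophage-like cells. The unthinned Ifng shares were 54.0% and 28.3%.

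H2-Ab1 at 782.5 against 135.4 CPM and H2-Eb1 at 501.9 against 70.6 also ranked, but both are macrophage genes. The H2-Ab1 level of T cell-like cells was 5.90% and 5.91% of that of macrophage-like cells of the same library. The levels of C1qa were 5.40% and 2.34%, those of Apoe 4.59% and 1.75%, and those of Spp1 33.6% and 34.1%.

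The 12 genes ranked first as higher in the non-responder library were Penk, Spp1, Gzmc, Klra1, Bmyc, Ikzf2, Gadd45g, Ass1, Foxp3, Mt2, Ramp1 and Gzmf. Penk (chromosome 4, 4133531 to 4138819), the proenkephalin gene, was at 8.10 CPM [1.67-23.7] against 462.1 [392.6-540.3]. Gzmc was at 40.5 against 626.9 CPM and Gzmf at 118.7 against 506.2. Ikzf2, which encodes the transcription factor Helios, was at 37.8 against 288.4 CPM, and Spp1 at 27.0 against 529.8. Bmyc had a log2 ratio of -4.13, Gadd45g -3.16, Ass1 -2.73, Ramp1 -2.71 and the metallothionein gene Mt2 -2.55. Klra1 had 1 count against 34, a log2 ratio of -5.21 [-10.56 to -2.64].

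**Figure D5:**
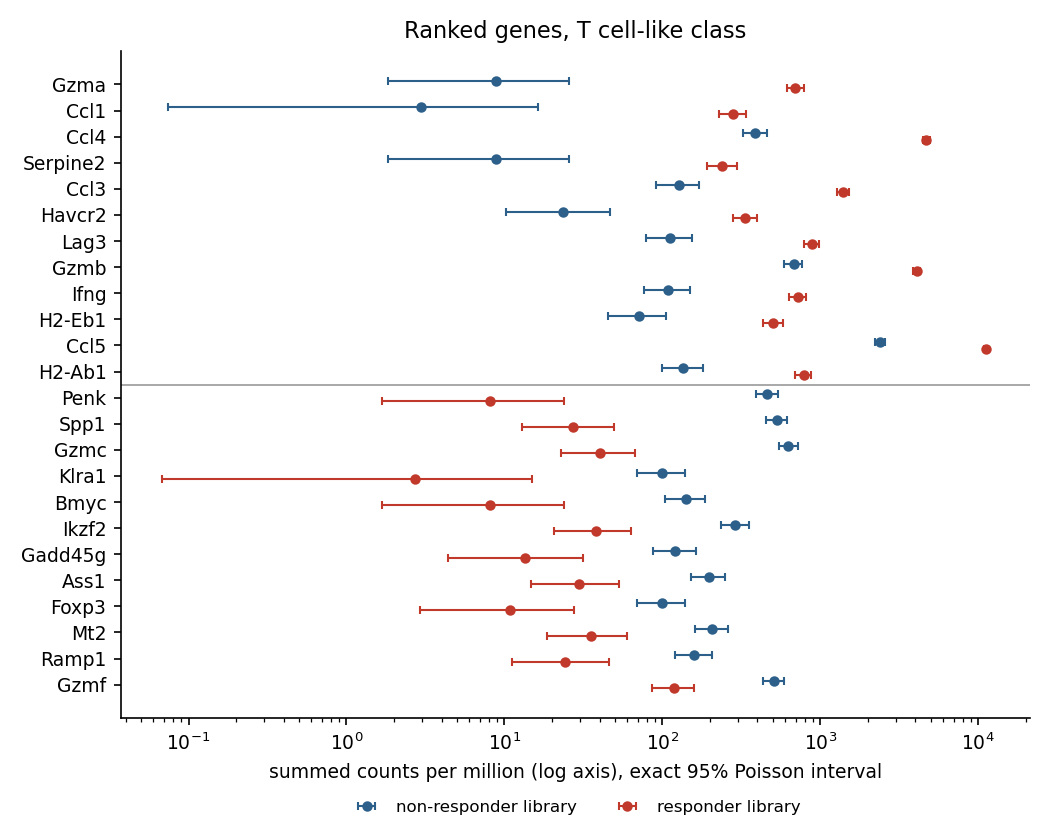
Summed counts in CPM (log axis) of the 24 ranked genes of the T cell-like class, with exact 95% Poisson intervals, in each library. Intervals are wider than in macrophage-like cells, as for Gzma at 693.5 against 8.83, Ccl4 at 4695 against 388.5 and Penk at 8.10 against 462.1.

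Of the cytotoxic effector list, 12 of 14 measured genes were higher in the responder library, with a median of 2.24 [0.19-3.40] at percentile 100. Gzmc and Gzmf were the exceptions. Exhaustion and inhibitory receptor genes were higher in 10 of 11, with a median of 1.35 [0.11-2.92] at percentile 100, while Tnfrsf9 was at 1198 against 1113 CPM and Tox at 75.6 against 105.95. The targets of imaging and therapy were higher in 4 of 4, with a median of 1.35 [0.24-1.42] at percentile 99.7. Cd8a was at 2183 against 812.3 CPM, Cd8b1 at 1816 against 709.3, Pdcd1 (chromosome 1, 94038305 to 94052553) at 1015 against 394.4 and Ptprc at 380.5 against 320.8. Itgam, Cd274 and Pdcd1lg2 had intervals that included 0. The 3 measured inflammatory chemokines, Ccl3, Ccl4 and Ccl5, had a median of 3.40 [2.23-3.58] at percentile 100. These genes are also in the cytotoxic effector list, so the values of the 2 lists are not independent. Interferon-gamma induced genes were higher in 9 of 9, with a median of 0.59 [0.47-1.33] at percentile 99.3, Irf1 at 210.5 against 64.7 CPM and Gbp7 at 170.0 against 64.7. MHC class I genes were higher in 12 of 13, with a median of 0.16 [0.05-0.52] at percentile 73.2 and Tap1 at 396.7 against 223.7 CPM. H2-T22 was at 715.1 against 382.6 CPM. Type I interferon genes had a median of 0.28 [-0.55 to 1.14] at percentile 81.7, with Zbp1 at 310.3 against 138.3 CPM and Ifit1 at 121.4 against 179.5.

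Regulatory T cell genes had a median of -0.47 [-2.78 to 1.98] at percentile 0.380, with Icos at 607.1 against 150.1 CPM and Ctla4 at 574.7 against 147.2. Dissociation stress genes had a median of -0.63 [-1.23 to 1.58] at percentile 0, with Fos at 345.4 against 815.3 CPM and Ier2 at 434.4 against 141.3. NF-kB genes were at -0.41 [-0.71 to 1.103] and percentile 0.890, with Tnfaip3 at 151.1 against 67.7 CPM. Naive and memory genes were at 0.35 [-1.34 to 1.60] and percentile 77.9, with Ltb at 599.0 against 194.2 CPM, Cd27 at 410.1 against 170.7 and Bcl2 at 167.3 against 429.7. Proliferation genes were at -0.13 [-0.54 to 0.35] and percentile 8.70, and oxidative phosphorylation genes at 0.01 [-0.06 to 0.44] and percentile 14.6. Glycolysis genes were at 0.28 [0.00 to 0.87] and percentile 88.9, and hypoxia genes at 0.18 [-0.15 to 0.85] and percentile 53.7 over 3 members. The 3 measured checkpoint ligands and suppressive genes were at 0.91 [-0.04 to 3.57] and percentile 98.9.

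Macrophage lists in this class are read beside the levels of macrophage RNA given above. MHC class II had a median of 1.53 [-0.01 to 2.74] at percentile 100 over 6 members, which was 0.26 in L4 alone and 0.84 with each library clustered on its own, C1q and resident-type genes 1.31 [1.19-1.57] at percentile 99.9 over 4, and lipid and lysosome genes 0.64 [-4.06 to 1.54] at percentile 96.0 over 5. Monocyte genes were at 0.24 [-0.44 to 0.90] and percentile 73.8 over 5. Too few members were measured of the NK cell (2) and matrix (1) lists. None was measured of the M1, M2, neutrophil, tumour epithelial, fibroblast, endothelial and erythroid lists.

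Several T cell values changed with the clusters compared. Within cluster L4 alone, the cytotoxic list had a median of 1.28 [0.24-3.87] with 9 of 10 members higher, exhaustion genes 0.31 [-0.59 to 1.28], the imaging and therapy targets 0.17 [-0.07 to 0.38] and MHC class I genes -0.06 [-0.24 to 0.23]. There Ccl3 had a log2 ratio of 3.93 [3.16-4.80], Ccl4 3.45 [2.84-4.11], Gzmb 3.04 [2.64-3.46] and Lag3 1.3004 [0.64-1.98], and Ifng 0.69 [-0.05 to 1.43]. Without L5, Penk had 3 counts against 1 and Foxp3 0 against 0, too few for a ratio, Ass1 and Ramp1 were -0.54 each and Gzmc was -1.84. Without L3, Klra1 had 0 counts against 0. With the mixed droplets counted in, the chemokine list was 0.80 and the exhaustion list 0.58. The interferon-gamma list was 1.37 there and 1.29998 without L5, against 0.59 in the class. Again with the mixed droplets counted in, Gzma was 3.40, Ccl1 2.60, Ccl4 2.22, Havcr2 2.07, Gzmb 1.65, Ccl3 1.51 and Ifng 1.29. In the same setting Mt2 was -1.45, Bmyc -1.05, Gadd45g -0.53 and Ass1 -0.46.

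In thinned T cell-like cells Ccl1 had 18 counts against 0, at least 2.32 against 3 counts, Ikzf2 was -4.58 and Gzmf -1.24. As a mean over cells Mt2 was -1.42 and Gzmf -1.38. With each library clustered on its own, Gzma was 2.66, H2-Eb1 1.53, Gzmc -2.45, Foxp3 -5.21 and Gzmf -1.18. Without the highest doublet scores, Gzma was 2.58, Spp1 -2.62, Ikzf2 -1.93, Foxp3 -1.42 and Gzmf -3.38. Several list medians in this class also changed sign. Over all alternatives dissociation stress ranged from -0.81 to 0.68, regulatory T cell genes from -0.85 to 0.67, NF-kB from -0.53 to 0.26 and naive and memory genes from -1.13 to 1.49. Hypoxia ranged from -0.41 to 0.32, monocyte genes from -0.497 to 0.35, lipid and lysosome genes from -0.23 to 0.74, and type I interferon from -0.06 to 1.24. Proliferation ranged from -0.497 to 0.14, oxidative phosphorylation from -0.055 to 0.35 and glycolysis from -0.0146 to 0.36.

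Ratios were then set side by side across classes. H2-Ab1 was at 2.53 in macrophage-like, 2.53 in T cell-like, 2.34 in mixed and 3.49 in fibroblast-like droplets, and at -0.02 [-0.10 to 0.05] in dendritic-like cells. Zbp1 was at 1.01, 1.17, 1.36 and 1.38 in the same order and at 1.16 in dendritic-like cells. Ifitm1, at 3.47 in macrophage-like cells, was at -0.37 [-0.86 to 0.13] in T cell-like and -0.78 [-1.06 to -0.49] in mixed droplets. Spp1 was at -4.27 in macrophage-like, -4.30 in T cell-like and -1.23 in fibroblast-like cells. Across genes, the ratios of macrophage-like cells had a Pearson correlation of 0.381 with those of T cell-like cells (1641 genes) and of 0.350 with those of fibroblast-like cells (3010 genes). Genes are not independent replicates, and the Spearman values were 0.348 and 0.308.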

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

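All tests in this part were chosen only after the result had been seen. The 4 results below are signals outside the compared classes or lists.

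The first was a group of 42 fibroblast-like cells, 20 in the non-responder and 22 in the responder library, although the sort was for CD45. Over both libraries they had Serpinh1 at 953 CPM, Dcn at 820, Col3a1 at 645, Sparc at 420 and Col6a1 at 232, against at most 1.495 CPM for each of these in macrophage-like cells. Other genes of the fibroblast list were low, with Pdgfra at 30.5 CPM, Pdgfrb at 22.3, Col1a1 at 8.27, Col1a2 at 1.91, Lum at 1.27, Col5a2 at 0.636 and Postn at 0, so the name rests on part of the list. Ptprc, the CD45 gene, was at 6.36 CPM against 159 in macrophage-like cells. The tables argue against fibroblasts of the host mice, since Xist (chromosome X, 103460366 to 103483254) was at 6.995 CPM [3.49-12.5] against 676 in macrophage-like cells, which came from the host. They argue against droplets shared with a macrophage, since the median droplet had 4 C1qa UMIs against 85 in a macrophage. Injected tumour cells may be the source and stay open, although the CD45 sort should remove them as it should fibroblasts. Of the 11 genes of the tumour epithelial list 0 reached 50 CPM, and the highest, Cdkn2a, was at 2.54. No table here shows whether MC38 cells carry these genes, so this decides nothing about them. Rhox5 at 532 CPM and H19 at 395, against 2.35 and 2.37 in macrophage-like cells, were seen after the cells had been named. Neither response group lacked these cells, and beyond the sources named above no explanation was tested.

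The second was a group of 134 droplets with the markers of both T cells and macrophages, 103 in the responder and 31 in the non-responder library. Pairs of 1 T cell and 1 macrophage stay open. The T cell part of the RNA, over that of a pair with the median UMIs of each class, was 0.867 in the responder and 1.34 in the non-responder library, so the libraries lay on either side of the value of 1 that a pair needs. Their median of 13424 UMIs in the responder library lay near the 13790 of a T cell and a macrophage added, while the non-responder values were 13562 and 16845.5. Random loading should pair other cells with macrophages as often as T cells, and free RNA should reach all droplets alike. Both were tested on droplets picked by T cell, NK or fibroblast genes alone, without macrophage genes, with at least 3, 3 and 10 UMIs of them. A droplet was counted as holding a macrophage's RNA by a cut of 66.5 C1q UMIs in the responder and 64.5 in the non-responder library. Of 279 droplets with T cell genes 43.0% [37.1-49.0] passed the cut. Of 23 with NK genes 0 did, which allows up to 14.8%, and of 26 with fibroblast genes 1 did, which allows up to 19.6%. With both libraries together this argues against random loading alone. Free RNA was not decided, since macrophage RNA below the cut did not count. C1qa was at 382 CPM in responder and 91.3 in non-responder NK cell-like cells, and at 273 and 124 in fibroblast-like cells. Free RNA at such levels lies under the cut in a droplet of median depth, though the deepest droplets may pass it. In the non-responder library alone the T cell value was 28.3% [19.4-38.6], with bounds of 24.7% for fibroblast and 17.6% for NK genes, so the fibroblast interval overlapped. In the responder library alone it was 50.3% [42.9-57.6], with bounds of 36.0% and 60.2%, so the NK interval of 4 droplets overlapped. Neither library alone thus set T cells apart from both. Most T cell droplets (187 of 279) were from the responder library and most NK droplets (19 of 23) from the non-responder library. T cells attached to macrophages may explain these droplets, a hypothesis that was not tested. For the higher responder value of 50.3% [42.9-57.6] the response group stays open as a reason. The number of cells loaded stays open beside it, since the responder library held 4425 barcodes against 2580.

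The third was cluster 17, with 44 cells, 2 in the non-responder and 42 in the responder library. Its median was 3216.5 UMIs with 0.0860% mitochondrial UMIs, its leading genes were Mmp13, Clec4d (a neutrophil marker) and Pla2g7, and C1qa was at 7040 CPM. The fourth was 19957 haemoglobin UMIs in the non-responder library against 50 in the responder library, with 3 barcodes above 1000. No explanation was tested for either.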

How the results depend on the processing

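No paired analysis was possible because each group had 1 library and the labels give no replicate numbers, and for the same reason leaving out a replicate and other splits of the samples did not apply. The alternatives on high doublet scores, single clusters and mixed droplets were chosen after seeing the data. Of 112 alternative values of class shares 91 stayed within the counting interval and 21 moved. Of 729 values of 45 list medians 698 stayed within the interval over members, 30 moved and 1 reversed, where reversed means a change of sign in a value whose interval excluded 0. That held for 16 lists. Of the 467 values of the other 29 lists 37 changed sign, in 20 lists. Of 2131 values of 158 gene ratios 1781 stayed within the counting interval, 343 moved and 7 reversed, all 7 in T cell-like cells. In 5 cases, among them Penk and Foxp3 without L5 and Klra1 without L3, both libraries had 3 counts or fewer and no ratio was given. None of the 312 values of the 24 ranked macrophage genes changed sign, and none of the 333 of the ranked T cell genes did. These genes had been picked from the same cells for intervals far from 0, so this says little. Equal weight per cluster was not applied to gene ratios, and within single shared clusters some ranked macrophage genes did change direction, as given above. Of the 2 compared classes the T cell-like one had fewer UMIs, 370597 and 339772. The cause of the moves below was not tested, except that equal weighting and left-out clusters change which cells are compared.

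Among shares in percent, resolution 0.5 gave 3.67 non-responder and 0.960 responder dendritic-like cells, and 1000 variable genes gave 4.06 and 0.960. Resolution 2.0 gave 0.297 fibroblast-like and 94.8 macrophage-like cells in the responder library. Clustering the libraries apart gave 0.983 dendritic-like, 93.01 macrophage-like, 0 NK cell-like and 0 fibroblast-like cells there. Requiring 1000 genes gave 94.9 macrophage-like responder cells, and leaving out high doublet scores gave 0.573 mixed non-responder droplets. Unnamed cells were 0 in both libraries at resolution 0.5, with 1000 variable genes and with 1000 genes required. In the responder library they were 0.206 at resolution 2.0 and 1.5996 with the libraries apart, where the non-responder library had 0.

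Among macrophage list medians, TMM scaling gave MHC class I 0.88, proliferation -0.16 and NF-kB 0.33, and a pseudocount of 1 CPM gave fibroblast genes -0.15. Equal weight per shared cluster gave MHC class I 0.29, interferon-gamma 0.37, type I interferon -0.69, lipid and lysosome -0.44, proliferation -0.0158 and NF-kB -0.071. Proliferation was -0.10 without cluster 3 and -0.51 without the dividing clusters.

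Among T cell list medians, C1q genes were 1.15 without high doublet scores, 1.57 thinned, 0.48 with members of at least 1 count, 0.71 with equal weight per cluster (which leaves L4 alone), 1.16 without L3 and 0.86 with mixed droplets. The imaging and therapy targets were 1.43 thinned, 1.45 as a mean over cells and 0.17 in L4. Chemokines were 0.57 with members of at least 1 count, 4.199 without L5 and 0.80 with mixed droplets, and hypoxia was -0.41 and -0.25 in the first and last of these. MHC class I reversed to -0.055 in L4, and type I interferon was 1.24 without L5. With mixed droplets interferon-gamma was 1.37, monocyte genes -0.50 and glycolysis -0.0146.

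Among T cell genes, H2afz reversed to 0.0060 and Nfkbia to 0.41 without L5. With mixed droplets Ctsd reversed to -0.31, Plac8 to -0.11, Ly6c2 to -0.30, Klre1 to -0.031 and Fos to 0.40.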

Other observations

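Of the tests in this part, that of a shift shared by all cells was chosen only after the result had been seen.

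The macrophage-like cells of the libraries hardly mixed when clustered together. Of their 15 nearest neighbours, the share from the other library was 0.142 of that expected under full mixing in the non-responder and 0.0587 in the responder library. For T cell-like cells the ratios were 0.287 and 0.308, and for mixed droplets 0.558 and 0.161, so low mixing was not particular to macrophage-like cells. Dendritic-like cells had 0.680 and 0.969, NK cell-like cells 0.5175 and 0.9775, and the 42 fibroblast-like cells 1.06 and 0.926. With only 4 responder NK cell-like cells, most of their 15 neighbours had to come from the other library, so 0.9775 says little about mixing. A difference in depth per cell is argued against for macrophage-like cells, since their ratios after thinning were 0.189 and 0.0679. The interferon and antigen presentation lists alone do not account for it, since without their 66 genes the ratios were 0.154 and 0.0705. A shift acting on all cells of a library alike would carry over in full to other types. The 71 genes that were 2-fold apart in macrophage-like cells had a median log2 ratio of 0.79 [0.42-1.23] in fibroblast-like cells, signed by the macrophage direction, against 1.496 in macrophage-like cells. This argues against such a shift as the whole of it, while a part may be shared, and free RNA was not separated from it. Group and library were the same split, so a difference of mouse, sort or library preparation that acts on macrophages stays open beside response to treatment.

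In macrophage clusters 7 and 10, 0 of 22 type I interferon genes were higher in the responder library, with medians of -1.60 [-2.38 to -0.82] and -1.82 [-2.42 to -1.08], while the class median was 0.16. The clusters held 24 and 29 non-responder cells. In the other shared clusters the medians were -0.09 in cluster 1, -0.06 in cluster 4 and 0.14 in cluster 9. Cells led by genes such as Oasl1, Ifit3 and Isg15 formed cluster 8, with 383 responder and 13 non-responder cells, outside this comparison.

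In fibroblast-like cells, 0 of 11 hypoxia genes were higher in the responder library, with a median of -2.18 [-3.61 to -1.43], and 0 of 14 glycolysis genes, with a median of -0.94 [-1.43 to -0.78]. Interferon-gamma induced genes were higher in 10 of 11, with a median of 0.88 [0.21-1.98], and MHC class I genes in 12 of 13, with a median of 0.51 [0.13-0.67]. Dissociation stress genes were higher in 12 of 13 as well, with a median of 0.80 [0.43-1.11] at percentile 100, so a difference in handling was not separated from these values. Beside these, C1qa in fibroblast-like cells was at 3.38% of the macrophage level in the responder and 1.82% in the non-responder library. In dendritic-like cells, of which the responder library had 11, MHC class II genes were higher in 1 of 10, with a median of -0.20 [-0.48 to -0.02] at percentile 43.6. The random lists themselves had a median of -0.18 there, so this was no drop specific to MHC class II. MHC class I genes were higher in 12 of 12, with a median of 0.61 [0.35-0.80]. In mixed droplets 15 of 15 type I interferon genes were higher, with a median of 1.401 [0.70-1.60]. These droplets came from different clusters, L0 with 21 non-responder and 1 responder droplets, L1 with 10 and 20 and L6 with 0 and 82, and their macrophage share was 0.659 in the non-responder and 0.758 in the responder library.

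Of all barcodes, 14 occurred in both libraries, and 0 of these fell in the same cluster in both.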
